A study of Mus musculus with 16 samples.

How the data were processed

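Per the labels, total RNA from the quadriceps of 16 male mice aged 8 weeks was labelled with Cy3 and hybridised to Agilent mouse arrays, 1 array per mouse. Per the file headers, each array was scanned in 1 channel and its spots were quantified with Agilent Feature Extraction 11.0.1.1, whereas the submitters' notes name version 9.5. How mice were assigned to slides and array positions was not given in the sources used here.

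The intensities used here are the deposited processed signals, which per the file headers were background-subtracted and detrended within each array and were not scaled between arrays. The deposited median signals of spots and local background, intensities with no correction per the file headers, served a single alternative. Per the file headers, marks of 0 or 1 state whether a spot was well above background, saturated or uneven. The authors' value table holds scores for 18324 spots. Each score was the deposited processed signal times 1 factor per array within 2%, rounded, with a 75th percentile of 100 on each of the 16 arrays. The scores were thus linear, larger for more signal, with no logarithm and no centring across arrays. The table's column medians ran from 22 to 25.

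Of 59305 spots other than controls, repeats of the same probe were averaged to 55681 probes. Probe names came from the RefSeq accession of each probe and a table of mouse gene symbols. A symbol was found for 28331 probes, and the 27350 probes without one were tested under their probe name. The file headers name mouse genome build mm9 and the table of symbols GRCm38.p6, so no coordinates are given. Spots marked as uneven were left out, which removed between 0.143% and 3.28% of the spots of an array. A probe was kept where it was well above background on every array of at least 1 group. That left 28568 probes of 21280 genes, 14149 of them with a symbol. For a gene with several kept probes the brightest probe stands, and the others are alternatives. Genes with fewer than 2 values in a group were not tested.

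Signals were taken as log2 and the 75th percentile of each array was subtracted. A linear model of 4 group means was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 12 residual degrees of freedom, prior degrees of freedom 3.24). Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene passed at an adjusted p under 0.05. The same model gave 5 contrasts: the effect of fasting in each genotype, the effect of the knockout in each feeding state, and the difference between the fasting effects (interaction). Its p-values describe the spread between the arrayed mice of each group and nothing beyond them. Where a probe was not well above background on any array of the lower group, a bound is given. It compares the mean of the higher group with the lowest signal that was well above background on those arrays, as "at least N-fold". For Galnt3, chosen by the rule below for the interaction, no value is given, since it was well above background on fasted WT arrays alone.

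In all, 29 gene lists were written from general knowledge of muscle, fasting and FoxO biology before the data were examined, 7 of them markers of other cell types. The comparisons, thresholds and most alternatives were also fixed before the data were examined. Lists were tested with limma's camera at its preset correlation of 0.01 between genes and Benjamini-Hochberg values over the 29 lists of a contrast. The preset treats the genes of a list as nearly independent, so each call is given with the adjusted p that camera gave with an estimated correlation. The estimate left 1 of 49 calls. A second test, fry, called 26 lists. It asks whether the genes of a list move, on balance, one way, without comparing them with other genes. Median, mean and camera's direction differed in sign for 0 of the 49 called lists and for 15 of the others, whose medians were at most 0.12 in size. Counts within lists are also given after adjustment over the list alone.

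Genes are named by a rule: Foxo1, Foxo3 and Foxo4; for each 2-group comparison the 8 genes with the largest rise and the 8 with the largest fall among those that passed and whose groups did not overlap; for the interaction the 8 highest and 8 lowest; and for each list up to 4 passing members with the largest change. Genes without an ordinary symbol were passed over, and some genes chosen by the rule are not reported here. A gene named outside this rule is said to have been chosen after its values were seen.

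The gene and list tests were run on simulated data with the group sizes and spread of these arrays. Simulated log2 changes of 0.5, 1 and 2 (WT fasting) were recovered for 7.46%, 49.3% and 92.4% of genes. Interactions of -1 and -0.5 were recovered for 10.6% and 0%. With 66 or 67 genes changed per size, passing took a lower unadjusted p than in real WT fasting, where recovery was not measured. Called were 1 to 6 of 21080 unchanged genes per contrast, the raised list and 0 of 28 unchanged lists. The list result does not carry over to real arrays, whose wrong splits called medians of 5 to 7.5 lists.

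Alternatives used quantile normalization, the array median, the value table, no filter or a stricter filter on dim probes, other probes of a gene, the slide or the replicate number as a block, each slide alone, limma's arrayWeights, other variance settings and thresholds, and leaving out each array in turn. Alternatives chosen after seeing the data were background correction by normexp (offset 50) on the median signals, scaling on probes well above background on all arrays, marked spots kept, a patch of spots left out, and the 2 arrays farthest from their groups left out. The files held no mean signal, which one planned correction needed. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, and tables were read with pandas 2.3.3 and numpy 2.4.6. Control spots, scanner images and probe coordinates were not used here.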

Results

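Gene expression was measured in the quadriceps muscle of wild-type (WT) mice and of mice without Foxo1, Foxo3 and Foxo4 in skeletal muscle (mFoxO-TKO), each fed or fasted for 24 h. The FoxO proteins are transcription factors that insulin signalling holds out of the nucleus, and the knockout came from a Cre recombinase under a skeletal actin promoter. Each of the 4 groups had 4 mice with 1 array each. The 16 arrays lay on 2 slides, with replicates 1 and 2 of every group on slide 1 and replicates 3 and 4 on slide 2. Within a slide all arrays of a group lay in 1 column, so an effect of array position and an effect of group cannot be told apart. The share of spots well above background ran from 45.0% (fasted mFoxO-TKO replicate 1) to 75.2% (fasted WT replicate 4), with 0 saturated spots. In what follows a change is a difference of group means on the log2 scale ± the standard error of the limma model, with n = 4 arrays per group. Values of 1 array were left out for Gabarapl1, Angptl4, Musk, Cry2, Slc2a1 and Pik3r1 (fasted mFoxO-TKO), Nop14 and Eif4ebp1 (fasted WT), Igfbp5 (fed WT) and Olfr1000 (fed mFoxO-TKO), and of 2 arrays for Col3a1 (fed WT and fasted mFoxO-TKO), so n = 3 in those groups.

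The first principal component of 19337 genes held 33.7% of the variance and set fasted WT muscle (scores from 47.6 to 73.2) apart from the other 3 groups. Fasted mFoxO-TKO muscle lay between (-1.98 to 27.8), above fed WT (-26.6 to -20.9) and fed mFoxO-TKO muscle (-54.9 to -39.2). On the second component (17.5%) slide 1 lay above slide 2 in every group. Fasted mFoxO-TKO replicate 1 stood apart at 87.2 (next highest 29.5). That array held a patch of 1974 spots (3.33%) where bright spots had lost signal, over the probes of Fbxo32 and Ptx3.

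**Figure D1:**
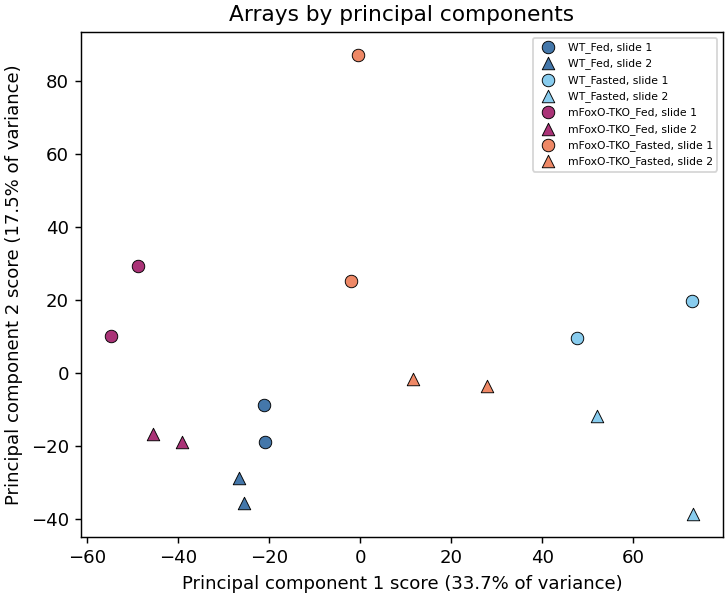
Scores of the 16 arrays on the first 2 principal components of log2 signal relative to each array's 75th percentile, 1 point per array, coloured by group and shaped by slide. Fasted mFoxO-TKO replicate 1 lies at 87.2 on the second component.

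Foxo1 and Foxo4 transcripts were lower in mFoxO-TKO muscle, as measured over the whole tissue. Foxo1 was lower by 1.76 ± 0.23 in fed mice (3.38-fold, adjusted p = 0.00113) and was lower by 3.399 ± 0.23 in fasted mice (10.6-fold, adjusted p = 3.16e-07), and its other probe was lower by 1.40 ± 0.27 and 2.74 ± 0.27 (adjusted p = 0.0195 and 1.2e-05). Foxo4 was not well above background on any mFoxO-TKO array, so it was at least 6.59-fold lower in fed and at least 6.12-fold lower in fasted mice, or at least 5.03-fold and 4.38-fold by its other probe. Foxo3 was read by 1 dim probe, well above background on 3 fed WT, 4 fasted WT, 3 fed mFoxO-TKO and 3 fasted mFoxO-TKO arrays, and its knockout differences of 0.74 ± 0.27 in fed mice (adjusted p = 0.299) and -0.75 ± 0.27 in fasted mice (adjusted p = 0.0976) did not pass. Where these probes lie relative to the deleted parts of the genes was not given in the sources used here, and a probe outside them checks nothing. Fasting raised Foxo1 by 2.34 ± 0.23 (5.06-fold, adjusted p = 7.7e-06) and Foxo3 by 2.08 ± 0.27 (adjusted p = 6.33e-05) in WT mice, whereas Foxo4 changed by 0.21 ± 0.29 (adjusted p = 0.694). In mFoxO-TKO mice the Foxo1 change of 0.70 ± 0.23 did not pass by the brighter probe (adjusted p = 0.0809) and the other probe's change of 1.09 ± 0.27 did (adjusted p = 0.0213).

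**Figure D2:**
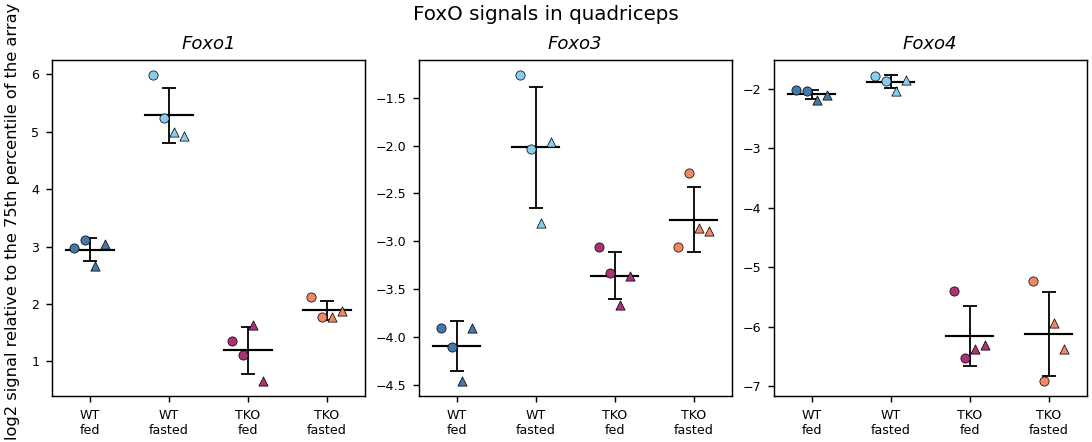
Log2 signal of Foxo1, Foxo3 and Foxo4 relative to the 75th percentile of each array, 1 point per array (circles slide 1, triangles slide 2) with the mean and SD of each group of 4. Foxo1 rose by 2.34 with fasting in WT mice.

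The response of WT muscle to 24 h without food was asked first. Genes of protein breakdown rose in fasted WT mice. Fbxo32 (atrogin-1) and Trim63 (MuRF1), ubiquitin ligases of muscle atrophy, rose by 3.67 ± 0.32 (12.7-fold) and 2.13 ± 0.33 (4.39-fold), each with an adjusted p of at most 3.31e-04 (3.43 by the other probe of Trim63). Cblb, a ligase that acts on insulin receptor substrate, rose by 2.03 ± 0.22 and Fbxo30 by 1.79 ± 0.16 (adjusted p at most 1.56e-05), although the dimmer probe of Cblb did not pass (adjusted p = 0.212). Of 18 ubiquitin ligases and atrophy genes 10 rose, 1 fell and 7 did not pass (11 and 1 adjusted over the list alone). The median of that list was 0.59 (0.59 with slide as a block, 0.62 and 0.51 within slides 1 and 2), at an adjusted p = 1.27e-05 and an adjusted p = 0.393 with an estimated correlation. The member that fell was Trim32, chosen here after its values were seen, at -0.56 ± 0.19 (adjusted p = 0.0431), a call lost without any 1 of 11 arrays. Among 32 proteasome subunits 12 rose and 20 did not pass (15 rose adjusted over the list alone). Psmd11 rose by 1.27 ± 0.16 and Psma1 by 1.01 ± 0.18 (adjusted p at most 0.00105). Proteasome genes had a median of 0.52 (0.52 with slide as a block, 0.57 and 0.48 within slides), at an adjusted p = 5.67e-07, or 0.383 with an estimated correlation. Of 30 autophagy and lysosome genes 12 rose and 18 did not pass (16 rose adjusted over the list alone). Depp1, a FoxO target linked to autophagy, rose by 5.44 ± 0.38 (43.6-fold), the autophagosome gene Gabarapl1 by 2.68 ± 0.20 (6.39-fold), the autophagy kinase gene Ulk1 by 1.99 ± 0.16 and the lysosomal protease gene Ctsl by 1.33 ± 0.16 (adjusted p at most 4.2e-05). Autophagy genes had a median of 0.49 (0.46 with slide as a block, 0.51 and 0.45 within slides), at an adjusted p = 2.74e-07, or 0.258 with an estimated correlation.

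Genes of fat use rose. Of 34 genes of fatty acid use 15 rose and 19 did not pass (17 rose adjusted over the list alone). They included the acyl-CoA thioesterases Acot1 (4.49 ± 0.75) and Acot2 (4.11 ± 0.23, 17.3-fold), and Angptl4 (2.39 ± 0.35), which inhibits lipoprotein lipase (adjusted p at most 5.94e-04). Their median was 0.57 (0.57 with slide as a block, 0.56 and 0.57 within slides), at an adjusted p = 1.9e-10 and an adjusted p = 0.108 with an estimated correlation. Of 16 genes of fatty acid synthesis 9 fell, 2 rose and 5 did not pass (9 and 2 adjusted over the list alone). Lower were Fasn (-2.88 ± 0.35, 7.34-fold lower), Elovl6 (-2.52 ± 0.24) and Scd2 (-1.68 ± 0.24; adjusted p at most 1.66e-04). The 2 that rose, chosen after their values were seen, were Dgat2, which makes triglyceride (0.94 ± 0.27, adjusted p = 0.0217, a call lost without any 1 of 4 arrays), and Acacb, whose product restrains fatty acid entry into mitochondria (0.90 ± 0.12, adjusted p = 1.07e-04). Fatty acid synthesis had a median of -1.06 (-1.06 with slide as a block, -1.30 and -0.70 within slides), at an adjusted p = 8.19e-05, or 0.383 with an estimated correlation. Cholesterol synthesis fell as well, with 8 of 19 genes lower, 1 higher and 10 not passing (11 and 2 adjusted over the list alone). An example was Sqle (-1.83 ± 0.25, adjusted p = 1.1e-04). Fdft1 alone of them rose, by 1.28 ± 0.23 (adjusted p = 8.38e-04) with its brightest probe, but its other probe gave -0.24. The cholesterol median was -0.48 (-0.48 with slide as a block, -0.49 and -0.45 within slides), at an adjusted p = 4.03e-04 and an adjusted p = 0.383 with an estimated correlation. Of 24 genes of glucose use 3 rose and 21 did not pass (2 rose adjusted over the list alone). They included the glucose transporter gene Slc2a1 (1.40 ± 0.21) and Pfkfb3 (1.14 ± 0.20), whose product promotes glycolysis (adjusted p at most 9.24e-04). The glucose list was not called (median 0.10, adjusted p = 0.336).

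Stress hormone and amino acid genes rose. Of 20 genes of the glucocorticoid response 17 rose and 3 did not pass (18 rose adjusted over the list alone). At the top stood Ddit4, an inhibitor of mTORC1 (3.86 ± 0.43, 14.5-fold), the metallothionein Mt2 (3.71 ± 0.47), the cell cycle inhibitor Cdkn1a (3.46 ± 0.26) and Cebpd (3.31 ± 0.38), each with an adjusted p of at most 6.09e-05. Glucocorticoid genes had a median of 1.76 (1.76 with slide as a block, 1.77 and 1.68 within slides), at an adjusted p = 7.8e-12, or 0.108 with an estimated correlation. Of 31 targets of the stress factor ATF4 12 rose, 1 fell and 18 did not pass (15 and 1 adjusted over the list alone). Gadd45a, a growth arrest gene linked to atrophy, rose by 2.91 ± 0.26 and Chac1, which degrades glutathione, by 2.40 ± 0.43 (adjusted p at most 9.53e-04). The fall of the serine enzyme gene Psph was -1.25 ± 0.23 (adjusted p = 0.00107, chosen after its values were seen). ATF4 targets had a median of 0.42 (0.42 with slide as a block, 0.52 and 0.47 within slides), at an adjusted p = 9e-05, or 0.383 with an estimated correlation. Of 30 genes of amino acid catabolism 8 rose and 22 did not pass (9 rose adjusted over the list alone). Examples were the glutamine synthetase gene Glul (2.21 ± 0.41) and Prodh (1.41 ± 0.32; adjusted p at most 0.00547). Amino acid genes had a median of 0.31 (0.32 with slide as a block, 0.35 and 0.25 within slides), at an adjusted p = 0.00542, or 0.574 with an estimated correlation.

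Insulin and IGF signalling was split, with 7 of 22 genes higher, 5 lower and 10 not passing (7 and 5 adjusted over the list alone) and no list call (median 0.12, adjusted p = 0.691). Sesn1, an mTORC1 inhibitor, rose by 3.16 ± 0.29 (8.96-fold), while the growth factor gene Igf1 fell by 2.01 ± 0.27 and Igfbp5 by 3.14 ± 0.41 (adjusted p at most 9.8e-05; -1.14, -1.06 and -0.77 by other probes of Igf1). Of 21 genes of ribosome biogenesis 10 rose and 11 did not pass (13 rose adjusted over the list alone). Myc rose by 1.91 ± 0.29 and Nop14 by 1.06 ± 0.16 (adjusted p at most 3.54e-04). Ribosome biogenesis had a median of 0.56 (0.56 with slide as a block, 0.61 and 0.48 within slides), at an adjusted p = 9.84e-05, or 0.383 with an estimated correlation. Of 19 antioxidant genes 7 rose, 1 fell and 11 did not pass (8 and 1 adjusted over the list alone). Higher were Hmox1 (1.47 ± 0.28) and Txnip (1.30 ± 0.21), which inhibits thioredoxin (adjusted p at most 0.00164). The extracellular dismutase gene Sod3, chosen after its values were seen, fell by 0.77 ± 0.18 (adjusted p = 0.0055). Antioxidant genes had a median of 0.53 (0.53 with slide as a block, 0.37 and 0.47 within slides), at an adjusted p = 0.00272, or 0.447 with an estimated correlation. Immediate early genes rose, 7 of 15 with 1 lower and 7 not passing (8 and 1 adjusted over the list alone). They were led by Maff (4.04 ± 0.26, 16.5-fold) and Btg2 (2.43 ± 0.38; adjusted p at most 3.52e-04). The 1 lower was Nr4a2 at -1.59 ± 0.52 (adjusted p = 0.04, lost without any 1 of 7 arrays and chosen after its values were seen). Early genes had a median of 0.80 (0.80 with slide as a block, 0.66 and 1.38 within slides), at an adjusted p = 0.00234 and an adjusted p = 0.383 with an estimated correlation. Odc1, which starts polyamine synthesis, rose by 2.08 ± 0.21 (adjusted p = 7.85e-06). It was 1 of 4 higher genes among 9 of polyamine metabolism (4 adjusted over the list alone), a list without a call (median 0.01, adjusted p = 0.176). Of 18 clock genes 5 rose, 2 fell and 11 did not pass (6 and 2 adjusted over the list alone; median 0.15, list adjusted p = 0.32). Examples were Cry2 (1.89 ± 0.24) and Ciart (3.02 ± 0.51; adjusted p at most 6.11e-04), and Ciart lost its call with another background correction (adjusted p = 0.0962).

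Matrix genes fell in fasted WT muscle. Of 23 genes of the extracellular matrix 14 fell, 1 rose and 8 did not pass (15 and 1 adjusted over the list alone). Lower were the collagen genes Col6a3 (-2.24 ± 0.37), Col6a2 (-2.11 ± 0.35) and Col3a1 (-1.98 ± 0.47; adjusted p at most 0.00797). Lox, which cross-links collagen and was chosen after its values were seen, rose by 1.58 ± 0.24 (adjusted p = 3.04e-04). Matrix genes had a median of -0.92 (-0.92 with slide as a block, -0.82 and -1.21 within slides), at an adjusted p = 2.29e-06, or 0.383 with an estimated correlation. The 7 fibroblast markers, none of them in another list, moved the same way, with 3 lower and 4 not passing (3 lower adjusted over the list alone), and Lum at -2.59 ± 0.33 (adjusted p = 6.64e-05). Fibroblast markers had a median of -0.45 (-0.45 with slide as a block, -0.65 and -0.25 within slides), at an adjusted p = 0.0208, or 0.503 with an estimated correlation. Myogenic and neuromuscular genes went both ways, with 2 higher, 2 lower and 14 of 18 not passing (2 and 2 adjusted over the list alone). Myod1, the myogenic regulator, fell by 2.97 ± 0.43 and the synapse kinase gene Musk rose by 2.46 ± 0.42 (adjusted p at most 7.83e-04; median 0.05, list adjusted p = 0.92). Outside the lists, the largest rises included Doc2b, a calcium sensor of vesicle release (6.06 ± 0.38), and Rnf39 (4.04 ± 0.52; adjusted p at most 6.99e-05), with S100g at least 4.26-fold higher. The largest falls included Phex (at least 4.93-fold lower), Fam78a (-4.07 ± 0.27, but -1.32 by its other probe), Fam83d (-3.92 ± 0.64), Apln and its receptor gene Aplnr (-3.69 ± 0.55 and -3.61 ± 0.63), Lrrc17 (-3.56 ± 0.47) and Ptx3 (-3.52 ± 0.40), each with an adjusted p of at most 7.94e-04.

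In all, 4426 of 21280 genes passed in fasted against fed WT mice, 2390 higher and 2036 lower (54% higher), and 1865 of them changed at least 2-fold. With slide as a block 5920 genes passed, within slide 1 alone 741 and within slide 2 alone 4744. All 63 genes named for this comparison kept their direction on both slides and passed with slide as a block, 37 of them within slide 1 and 57 within slide 2. The balance of rises and falls depended on the setting, with 62.55% of the passing genes higher without fasted WT replicate 3, 40.5% higher in the authors' value table and 37.5% when scaled on probes well above background on all arrays, which moved the median of all genes from 0.02 to -0.11.

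The same fast was then asked of mFoxO-TKO muscle. Fat use genes rose there too. Of 34 genes of fatty acid use 16 rose and 18 did not pass (22 rose adjusted over the list alone). Acot1 stood at 4.17 ± 0.75, Acot2 at 3.77 ± 0.23 (13.7-fold) and the lipid droplet gene Plin5 at 2.45 ± 0.21 (adjusted p at most 0.00331). Their median was 0.60 (0.64 with slide as a block, 0.51 and 0.77 within slides), at an adjusted p = 2.62e-16 and an adjusted p = 0.0373 with an estimated correlation. Glucocorticoid genes rose, 13 of 20 with 7 not passing (16 adjusted over the list alone). They included Lcn2 (lipocalin 2, 4.65 ± 0.44, 25.1-fold), Ddit4 (3.08 ± 0.43) and Cdkn1a (2.87 ± 0.26; adjusted p at most 6.5e-04). The glucocorticoid median was 1.18 (1.24 with slide as a block, 1.23 and 1.12 within slides), at an adjusted p = 3.04e-13 and an adjusted p = 0.0826 with an estimated correlation. Fbxo32 rose by 2.19 ± 0.32 (4.58-fold), or by 2.05 without the spots of the patch, Trim63 by 1.89 ± 0.33 and Cblb by 1.79 ± 0.22 (adjusted p at most 0.0028; 0.073 for the dimmer probe of Cblb). Among the 18 ubiquitin ligases and atrophy genes 6 rose and 12 did not pass (7 rose adjusted over the list alone). Atrophy genes had a median of 0.36 (0.36 with slide as a block, 0.42 and 0.31 within slides), at an adjusted p = 1.68e-05 and an adjusted p = 0.606 with an estimated correlation.

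Few other genes of protein breakdown passed in mFoxO-TKO muscle. Of the 32 proteasome subunits 1 passed, Psmd11, at 0.72 ± 0.16 (adjusted p = 0.0102, or 0.0629 with only these 2 groups in the model), and 31 did not (1 rose adjusted over the list alone, and 9 at an unadjusted p under 0.05). Proteasome genes here had a median of 0.21 (0.21 with slide as a block, 0.25 and 0.17 within slides), at an adjusted p = 0.028 and an adjusted p = 0.749 with an estimated correlation. Of the 30 autophagy genes 5 rose and 25 did not pass (6 rose adjusted over the list alone, and 11 at an unadjusted p under 0.05). Depp1 stood at 1.70 ± 0.38 and Gabarapl1 at 0.96 ± 0.21 (adjusted p at most 0.0128). Depp1 lost its call with only these 2 groups in the model (adjusted p = 0.0607) and Gabarapl1 without fasted mFoxO-TKO replicate 3 (adjusted p = 0.0537). Autophagy genes had a median of 0.25 here (0.22 with slide as a block, 0.26 and 0.18 within slides), at an adjusted p = 0.00932 and an adjusted p = 0.688 with an estimated correlation. Amino acid catabolism rose with 4 of 30 genes (4 adjusted over the list alone) and 26 not passing, such as Prodh at 1.98 ± 0.32 (adjusted p = 0.0017). Amino acid genes here had a median of 0.24 (0.24 with slide as a block, 0.21 and 0.26 within slides), at an adjusted p = 0.017 and an adjusted p = 0.749 with an estimated correlation. Clock genes rose with 6 of 18 (7 adjusted over the list alone) and 12 not passing. The clock median was 0.31 (0.31 with slide as a block, 0.37 and 0.21 within slides), at an adjusted p = 0.0321 and an adjusted p = 0.458 with an estimated correlation. In the lists of ATF4 targets, ribosome biogenesis, antioxidants and immediate early genes 3, 1, 0 and 2 genes rose and 0 fell (4, 1, 0 and 5 rose and 2 immediate early genes fell adjusted over each list alone), without a list call (adjusted p = 0.0971, 0.0575, 0.373 and 0.62). The 0 antioxidant genes are limma's count, against 2 higher and 0 lower at an unadjusted p under 0.05. Pfkfb3 fell by 0.92 ± 0.20 (adjusted p = 0.0109, or 0.224 for its dimmer probe), the only 1 of 24 genes of glucose use that passed (1 adjusted over the list alone).

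Lipid synthesis and matrix genes fell in fasted mFoxO-TKO muscle. Of 16 genes of fatty acid synthesis 6 fell, 2 rose and 8 did not pass (7 and 3 adjusted over the list alone). Scd2 stood at -2.44 ± 0.24, Elovl6 at -2.03 ± 0.24 and Fasn at -2.02 ± 0.35 against Dgat2 at 1.63 ± 0.27 and Acacb at 0.78 ± 0.12 (adjusted p at most 0.00239; the last pair chosen after their values were seen). Fatty acid synthesis had a median of -0.19 here (-0.19 with slide as a block, -0.11 and -0.53 within slides), at an adjusted p = 0.0209 and an adjusted p = 0.738 with an estimated correlation. Of 19 cholesterol genes 5 fell and 14 did not pass (6 lower and 1 higher adjusted over the list alone). Sqle stood at -1.59 ± 0.25 (adjusted p = 0.00142). The cholesterol median here was -0.30 (-0.30 with slide as a block, -0.32 and -0.45 within slides), at an adjusted p = 9.62e-05 and an adjusted p = 0.458 with an estimated correlation. Of 23 matrix genes 11 fell, 1 rose and 11 did not pass (11 and 1 adjusted over the list alone). Col6a3 stood at -1.97 ± 0.37 and Col3a1 at -1.96 ± 0.47 (adjusted p at most 0.0193; Col3a1 lost without any 1 of 4 arrays) and Lox at 1.53 ± 0.24 (adjusted p = 0.00142, chosen after its values were seen). Matrix genes had a median of -0.82 here (-0.82 with slide as a block, -0.26 and -1.10 within slides), at an adjusted p = 1.68e-05 and an adjusted p = 0.606 with an estimated correlation. Fibroblast markers moved with them, 2 of 7 lower and 5 not passing (2 lower adjusted over the list alone), with Lum at -2.18 ± 0.33 (adjusted p = 0.0012). Their median was -0.51 (-0.51 with slide as a block, -0.18 and -0.84 within slides), at an adjusted p = 0.00552 and an adjusted p = 0.606 with an estimated correlation. Macrophage markers, 13 of 14 measured and none in another list, had a median of -0.66 (-0.66 with slide as a block, -0.72 and -0.44 within slides), at an adjusted p = 0.028 and an adjusted p = 0.749 with an estimated correlation. Of these, chosen after their values were seen, Adgre1 (-1.39 ± 0.33, adjusted p = 0.0165, or -0.46 by its other probe) and Cd74 (-1.27 ± 0.37, adjusted p = 0.0453) fell and Itgam rose (0.59 ± 0.12, adjusted p = 0.0088). Another 10 did not pass (1 higher and 3 lower adjusted over the list alone), and the calls of Adgre1 and Cd74 were lost without any 1 of 2 and 11 arrays. In WT mice the macrophage median was -0.54 with fasting (adjusted p = 0.327).

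Some genes of muscle development were lower in fasted than in fed mFoxO-TKO muscle. The embryonic myosin gene Myh3 fell by 3.17 ± 0.88 (8.99-fold, adjusted p = 0.0355, lost without any 1 of 7 arrays), Mymk, which drives myoblast fusion, by 2.74 ± 0.56, the imprinted growth gene Mest by 3.30 ± 0.42 and Dclk1 by 3.41 ± 0.58 (adjusted p at most 0.00732). On the fed side these 4 were higher on replicates 1 to 3 than on replicate 4 (Myh3 log2 signal 6.34, 5.96 and 5.50 against 0.60). Mest and Dclk1 also fell in WT mice (log2 signal at most -1.48 and -2.82 fasted, at least -0.19 and -0.84 fed). Myogenic and neuromuscular genes as a list were not called (2 higher, 2 lower and 14 not passing, or 2 and 5 adjusted over the list alone, median -0.13, adjusted p = 0.373). Igf1 fell by 1.72 ± 0.27 (adjusted p = 0.0014; -1.30, -1.02 and -0.97 by other probes), in a list of insulin and IGF signalling with 1 higher, 5 lower and 16 not passing (4 and 6 adjusted over the list alone, median -0.18, adjusted p = 0.141). Further large rises were those of Gpr179 (3.50 ± 0.34), Mlph (3.397 ± 0.42), Odf3l2 (3.27 ± 0.50), Doc2b (3.22 ± 0.38) and Kiss1 (3.89 ± 0.99), and further falls those of Lrrc17 (-3.28 ± 0.47), Mup2 (-3.12 ± 0.59) and Ppm1n (-2.76 ± 0.35), each with an adjusted p of at most 0.0235. Adamts17 was at least 5.27-fold lower and Syt13 at least 3.09-fold lower.

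In mFoxO-TKO mice 1814 of 21280 genes passed with fasting, 914 higher and 900 lower (50.4% higher), and 876 changed at least 2-fold. With slide as a block 2800 genes passed, within slide 1 alone 67 and within slide 2 alone 1611. All 42 genes named for this comparison kept their direction on both slides and passed with slide as a block, 10 of them within slide 1 and 31 within slide 2. Of the named genes 6 lost their call without some 1 array and 12 in another setting, among them Kiss1 without any 1 of 4 arrays. Adamts17 and Syt13 lost theirs with another background correction (adjusted p = 0.0626 and 0.187), and that correction put 63.8% of the passing genes higher with a median of all genes of 0.10. The balance turned the other way without fasted mFoxO-TKO replicate 1 (35.9% higher), with the 2 arrays farthest from their groups left out (36.0%) and within slide 1 alone (34.3%).

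How much of the WT response remained without FoxO was asked next. Over the 1865 genes that changed at least 2-fold in WT mice, the median change in size and direction was 1.41 in WT and 0.79 in mFoxO-TKO mice, a share of 56.0%. Within replicate numbers 1 to 4 it was 0.36, 0.58, 0.65 and 0.55. Within slides 1 and 2 it was 41.7% and 56.2%, and with slide as a block 56.6%. Genes chosen on slide 1 and measured on slide 2 gave 58.0%, the reverse 46.1%. Choice by WT change may lower the share (a simulated 0.5 gave 0.4623). Of the 1865 genes 1749 kept their direction in mFoxO-TKO mice. The interaction passed against the WT change for 206 and along it for 1. Across all genes (not independent replicates) both changes correlated with r = 0.623. Both comparisons, which share no arrays, called 650 genes higher (103 expected if independent) and 643 lower (86.1 expected), and 9 in opposite directions.

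**Figure D3:**
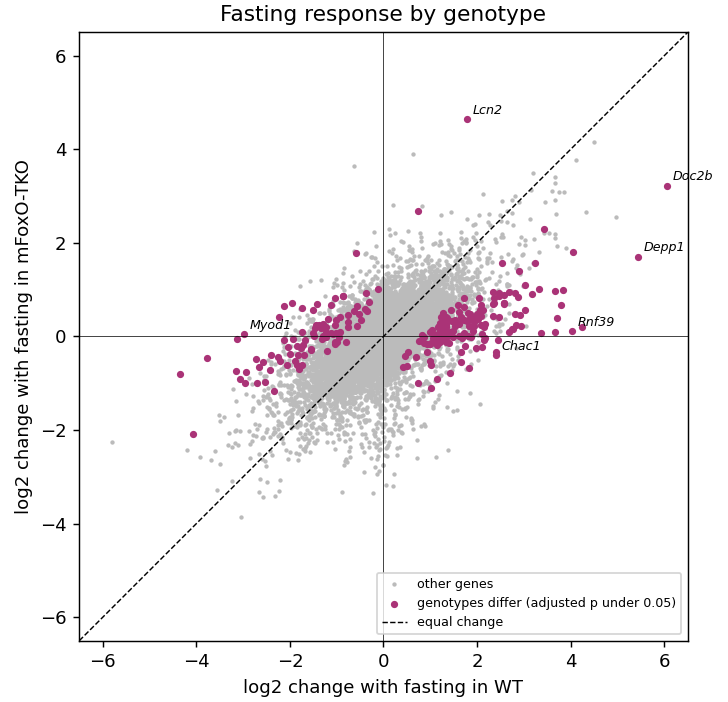
Log2 change with fasting in WT mice (x axis) against mFoxO-TKO mice (y axis), 1 point per gene, with genes whose interaction passed in purple and a dashed line of equal change. Over the 1865 genes with a 2-fold change in WT mice the median was 1.41 in WT and 0.79 in mFoxO-TKO mice.

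What the knockout changes in fed muscle was the next comparison. Some genes of muscle development were higher in fed mFoxO-TKO mice. Myh3 was higher by 4.29 ± 0.88 (19.6-fold, adjusted p = 0.0267), at 5.88 within slide 1 and 2.70 within slide 2, the acetylcholine receptor genes Chrna1 and Chrnd by 1.51 ± 0.34 and 1.09 ± 0.23, the adhesion gene Ncam1 by 1.06 ± 0.24 and the fetal growth factor gene Igf2 by 1.48 ± 0.33 (adjusted p at most 0.0483). Of 18 myogenic and neuromuscular genes 4 rose and 14 did not pass (7 rose adjusted over the list alone). The myogenic list had a median of 0.39 (0.39 with slide as a block, 0.52 and 0.28 within slides), at an adjusted p = 0.00163 and an adjusted p = 0.906 with an estimated correlation. Mest (1.71 ± 0.42, adjusted p = 0.0721), Dclk1 (2.32 ± 0.58, adjusted p = 0.0784) and Mymk (2.37 ± 0.56, adjusted p = 0.0638), chosen after their values were seen, did not pass. The rise lay on 3 of the 4 mFoxO-TKO arrays, with medians over these 8 genes of 2.28, 2.17 and 1.498 above fed WT for replicates 1 to 3 and 0.30 for replicate 4. Macrophage markers moved with this group and had a median of 0.47 (0.47 with slide as a block, 0.82 and 0.31 within slides), at an adjusted p = 0.00209 and an adjusted p = 0.906 with an estimated correlation. Of the 13 markers 0 passed in limma (0 adjusted over the list alone), against 3 higher at an unadjusted p under 0.05. The calls of Myh3, Chrna1, Chrnd, Ncam1 and Igf2 were each lost without any 1 of at least 7 arrays.

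Few genes of the metabolic lists passed in fed mFoxO-TKO muscle. Pfkfb3 was lower by 1.82 ± 0.20 (3.53-fold, adjusted p = 1.66e-04), the 1 gene of 24 of glucose use that passed (1 adjusted over the list alone, median -0.05, list adjusted p = 0.292). Gpt2, an alanine aminotransferase gene, fell by 0.72 ± 0.14 (adjusted p = 0.0214), as the 1 of 30 amino acid genes that passed (2 lower adjusted over the list alone). The amino acid list had a median of -0.18 (-0.19 with slide as a block, -0.18 and -0.20 within slides), at an adjusted p = 8.86e-04 and an adjusted p = 0.906 with an estimated correlation. The list of 18 clock genes had a median of -0.30 (-0.30 with slide as a block, -0.15 and -0.27 within slides), at an adjusted p = 0.00209 and an adjusted p = 0.322 with an estimated correlation. Fatty acid use had a median of -0.13 (-0.13 with slide as a block, -0.07 and -0.11 within slides), at an adjusted p = 0.0469 and an adjusted p = 0.906 with an estimated correlation. Of its 34 genes 0 passed in limma (1 lower adjusted over the list alone), against 3 lower at an unadjusted p under 0.05. Fatty acid synthesis had a median of -0.30 (-0.30 with slide as a block, -0.42 and -0.11 within slides), at an adjusted p = 0.0469 and an adjusted p = 0.906 with an estimated correlation. The 1 gene of it that passed, the desaturase gene Scd2, went against the list at 1.14 ± 0.24 (adjusted p = 0.0313; 1 higher adjusted over the list alone). Single members of other lists passed as well, namely the polyamine enzyme gene Smox (-1.48 ± 0.25), the glutathione peroxidase gene Gpx3 (-1.43 ± 0.30), the proteasome activator gene Psme4 (-0.77 ± 0.14), Fdft1 (-1.13 ± 0.23) and Mt2 (2.55 ± 0.47), each with an adjusted p of at most 0.0285. Among ubiquitin ligases, autophagy genes and ATF4 targets 0 genes passed in limma (0 adjusted over each list alone), with list medians of -0.01, -0.13 and -0.10 (adjusted p = 0.123, 0.0635 and 0.665), against 4 lower, 1 lower, and 3 higher and 2 lower at an unadjusted p under 0.05.

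Olfactory receptor genes gave the largest differences in fed mice. Olfr996 was at least 132-fold, Olfr1000 at least 65.6-fold and Olfr998 at least 22.3-fold higher in fed mFoxO-TKO mice, and Olfr437 was higher by 4.09 ± 0.43. So were the hepatokine gene Fgl1 (4.57 ± 0.43, 23.8-fold) and the cilia gene Maats1 (3.99 ± 0.31; adjusted p at most 2.81e-05). Lower were Tspan8 (-3.21 ± 0.19), the potassium channel gene Kcnab1 (-3.17 ± 0.30), Htra4 (-3.05 ± 0.32), Fam83d (-2.99 ± 0.64), Igf2bp3 (-2.62 ± 0.41) and Dnase1 (-2.40 ± 0.49), each with an adjusted p of at most 0.0349. Ccdc192 was at least 1.49-fold lower. In all 217 of 21280 genes passed, 108 higher and 109 lower (49.8% higher), and 164 differed at least 2-fold. With slide as a block 422 genes passed, within slide 1 alone 239 (83.3% higher) and within slide 2 alone 33 (30.3% higher). All 27 genes named for this comparison kept their direction on both slides and passed with slide as a block, 18 of them within slide 1 and 8 within slide 2. Of these 12 lost their call without some 1 array and 15 in another setting. Without fed mFoxO-TKO replicate 1 34.6% of the passing genes were higher, and without its replicate 4 66.4%. The count itself fell below 217 to 105 without fed WT replicate 2 and to 133 with another background correction, which also ended the calls of Igf2bp3, Ccdc192 and Dnase1 (adjusted p = 0.654, 0.861 and 0.304).

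Genes of protein breakdown were lower in fasted mFoxO-TKO than in fasted WT mice. Fbxo32 was lower by 2.17 ± 0.32 (4.51-fold), or by 2.31 without the spots of the patch, Fbxo30 by 1.39 ± 0.16 (adjusted p at most 3.91e-04) and Trim63 by 1.11 ± 0.33 (adjusted p = 0.0489, lost without any 1 of 14 arrays, or -2.38 by its other probe). Of 18 ubiquitin ligases and atrophy genes 5 fell and 13 did not pass (8 lower adjusted over the list alone). Atrophy genes had a median here of -0.27 (-0.27 with slide as a block, -0.34 and -0.26 within slides), at an adjusted p = 0.00507 and an adjusted p = 0.795 with an estimated correlation. Of 32 proteasome subunits 6 fell and 26 did not pass (8 lower adjusted over the list alone). Psme4 stood at -0.97 ± 0.14 and Psmd11 at -0.69 ± 0.16 (adjusted p at most 0.0103, but 0.116 for Psmd11 with only these 2 groups in the model). Proteasome subunits had a median of -0.46 (-0.46 with slide as a block, -0.37 and -0.47 within slides), at an adjusted p = 9.03e-08, or 0.72 with an estimated correlation. Of 30 autophagy genes 9 fell and 21 did not pass (9 lower adjusted over the list alone). Lower were Depp1 (-4.09 ± 0.38, 17.0-fold lower), Gabarapl1 (-2.04 ± 0.21, 4.10-fold lower), Ulk1 (-1.91 ± 0.16) and Ctsl (-1.41 ± 0.16; adjusted p at most 4.11e-05). Autophagy genes had a median of -0.27 in this comparison (-0.27 with slide as a block, -0.28 and -0.35 within slides), at an adjusted p = 6.58e-08 and an adjusted p = 0.54 with an estimated correlation.

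ATF4 targets, antioxidant genes and immediate early genes were lower as well in fasted mFoxO-TKO mice. Of 31 ATF4 targets 5 fell and 26 did not pass (8 lower and 1 higher adjusted over the list alone). Chac1 stood at -3.95 ± 0.43 (15.4-fold lower), Gadd45a at -2.45 ± 0.26 and the translation inhibitor gene Eif4ebp1 at -1.83 ± 0.31 (adjusted p at most 0.00134). The ATF4 median was -0.35 (-0.35 with slide as a block, -0.30 and -0.34 within slides), at an adjusted p = 4.76e-04, or 0.72 with an estimated correlation. Of 19 antioxidant genes 6 fell and 13 did not pass (8 lower and 1 higher adjusted over the list alone). Lower were Gclm, which makes glutathione (-2.69 ± 0.45), Gpx3 (-1.56 ± 0.30) and Txnrd1 (-0.98 ± 0.17; adjusted p at most 0.00276). The antioxidant median was -0.54 (-0.54 with slide as a block, -0.46 and -0.35 within slides), at an adjusted p = 4.76e-04, or 0.72 with an estimated correlation. Immediate early genes fell, 4 of 15 with 11 not passing (4 lower adjusted over the list alone). Maff stood at -2.49 ± 0.26 and Ier3 at -2.20 ± 0.25 (adjusted p at most 3.63e-05). The immediate early median was -0.41 (-0.41 with slide as a block, -0.45 and -0.31 within slides), at an adjusted p = 0.00788, or 0.72 with an estimated correlation. Odc1 fell by 2.40 ± 0.21 (adjusted p = 3.77e-06), the 1 of 9 polyamine genes that passed (2 lower adjusted over the list alone). The polyamine median was -0.38 (-0.38 with slide as a block, -0.29 and -0.41 within slides), at an adjusted p = 0.00788, or 0.72 with an estimated correlation. Amino acid catabolism had 3 lower, 1 higher and 26 not passing (3 and 1 adjusted over the list alone). The amino acid median was -0.40 (-0.40 with slide as a block, -0.47 and -0.18 within slides), at an adjusted p = 0.0012 and an adjusted p = 0.72 with an estimated correlation. Among them, and chosen after their values were seen, Aass fell by 1.24 ± 0.35 (adjusted p = 0.0356, lost without any 1 of 5 arrays) and the alanine aminotransferase gene Gpt rose by 0.94 ± 0.19 (adjusted p = 0.00685, or 0.129 with marked spots kept). Of 23 matrix genes 1 rose and 22 did not pass (1 higher adjusted over the list alone), Col5a1 at 1.01 ± 0.26 (adjusted p = 0.0189, chosen after its values were seen, lost without 1 array). The matrix median was 0.35 (0.35 with slide as a block, 0.39 and 0.23 within slides), at an adjusted p = 0.00897 and an adjusted p = 0.795 with an estimated correlation. Fibroblast markers had a median of 0.10 beside it (adjusted p = 0.858) and macrophage markers a median of 0.40 (adjusted p = 0.22).

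Lists without a call in fasted mice held single genes that differed. Of 22 insulin and IGF genes 3 rose, 5 fell and 14 did not pass (3 and 6 adjusted over the list alone, median -0.21, list adjusted p = 0.0915). Sesn1 stood at -2.72 ± 0.29 (6.61-fold lower), the receptor gene Igf1r at -1.51 ± 0.18 and Igfbp5 at 1.74 ± 0.38 (adjusted p at most 0.00806). Of 20 glucocorticoid genes 4 fell, 2 rose and 14 did not pass (9 and 2 adjusted over the list alone, median -0.44, list adjusted p = 0.0536). Klf15 stood at -1.73 ± 0.28 against Lcn2 at 3.74 ± 0.44 (13.3-fold) and Pik3r1 at 1.56 ± 0.27 (adjusted p at most 0.00171). Myod1 was higher by 3.41 ± 0.43 (10.7-fold, adjusted p = 9.3e-05), in a myogenic list with 1 higher, 1 lower and 16 not passing (1 and 1 adjusted over the list alone, median 0.43, list adjusted p = 0.166). Pfkfb3 was lower by 3.88 ± 0.20 (14.7-fold, adjusted p = 2.51e-08), as 1 of 2 lower genes among 24 of glucose use (2 adjusted over the list alone, median -0.01, list adjusted p = 0.747). In fatty acid use 2 of 34 genes fell and 32 did not pass (2 lower adjusted over the list alone, median -0.06, list adjusted p = 0.308). These were the triglyceride lipase gene Pnpla2 (-0.74 ± 0.16) and Acot2 (-0.91 ± 0.23; adjusted p at most 0.0208, Acot2 lost without any 1 of 3 arrays). In fatty acid synthesis 1 gene rose, 1 fell and 14 did not pass (1 and 1 adjusted over the list alone, median 0.19, list adjusted p = 0.337). Pnpla3, chosen after its values were seen, rose by 1.99 ± 0.37 (adjusted p = 0.00246, or 1.21 by its other probe). In cholesterol synthesis 2 rose, 2 fell and 15 did not pass (4 and 2 adjusted over the list alone, median 0.14, list adjusted p = 0.321). Fdft1 stood at -2.10 ± 0.23 (adjusted p = 2.46e-05), but at -0.85 by its other probe. Of 18 clock genes 3 fell and 15 did not pass (3 lower adjusted over the list alone, median -0.24, list adjusted p = 0.15). Cry2 stood at -1.64 ± 0.26 (adjusted p = 9.02e-04). Of 21 ribosome biogenesis genes 1 fell and 20 did not pass (1 lower adjusted over the list alone, median -0.23, list adjusted p = 0.05).

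The largest differences in fasted mice again included Olfr996 (at least 42.8-fold higher) and Olfr1000 (at least 39.7-fold higher), with Olfr998 at 4.27 ± 0.46 and Fgl1 at least 6.51-fold higher. The acetylcholine receptor gene Chrna9 was higher by 5.45 ± 0.76 (43.6-fold) and the water channel gene Aqp4 by 3.86 ± 0.28, each with an adjusted p of at most 2.59e-04. The amino acid transporter gene Slc43a1 (-4.17 ± 0.26, 18.0-fold lower), Rnf39 (-4.02 ± 0.52), Ctxn3 (-3.91 ± 0.30) and Tmem132e (-3.75 ± 0.27) were lower, each with an adjusted p of at most 1.35e-04. In all 1991 of 21280 genes passed, 934 higher and 1057 lower (46.9% higher), and 936 differed at least 2-fold. Together with the fed comparison, which shares no arrays with it, 72 genes were higher (4.74 expected if independent), 85 lower (5.41 expected) and 1 opposite, and r across genes was 0.447. With slide as a block 3027 genes passed, within slide 1 alone 352 and within slide 2 alone 1832. All 45 genes named for this comparison kept their direction on both slides and passed with slide as a block, 23 of them within slide 1 and 40 within slide 2. Of these 4 lost their call without some 1 array and 9 in another setting. The balance of directions moved both ways, with 60.0% of the passing genes higher when scaled on probes well above background on all arrays, 35.2% without fasted mFoxO-TKO replicate 1, 34.95% with arrayWeights and 26.9% with the 2 arrays farthest from their groups left out, which moved the median of all genes from 0.04 to -0.11.

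Whether fasting acts differently in the absence of FoxO was tested by the interaction, in which a negative value means a smaller rise or a larger fall with fasting in mFoxO-TKO mice. Genes of autophagy rose less in them. Of 30 autophagy genes 6 had a negative interaction that passed and 24 did not pass (8 adjusted over the list alone). Depp1 stood at -3.74 ± 0.54, Gabarapl1 at -1.72 ± 0.29, Ulk1 at -1.57 ± 0.23 and Ctsl at -1.28 ± 0.23 (adjusted p at most 0.0126). The autophagy median was -0.28 (-0.28 with slide as a block, -0.32 and -0.26 within slides), at an adjusted p = 2.51e-06 and an adjusted p = 0.774 with an estimated correlation. Among the 18 ubiquitin ligases and atrophy genes Fbxo30 alone passed (-1.47 ± 0.23, adjusted p = 0.00557; 4 negative and 1 positive adjusted over the list alone). The atrophy list was not called (median -0.09, adjusted p = 0.0576). ATF4 targets had 3 negative and 28 not passing (3 negative adjusted over the list alone). Gadd45a stood at -2.46 ± 0.37, Chac1 at -2.80 ± 0.61 and the transporter gene Slc7a1 at -0.90 ± 0.21 (adjusted p at most 0.0483). The ATF4 list had a median of -0.34 (-0.34 with slide as a block, -0.32 and -0.37 within slides), at an adjusted p = 7.37e-04 and an adjusted p = 0.82 with an estimated correlation. Immediate early genes had 3 negative and 12 not passing (4 negative adjusted over the list alone). Maff stood at -2.24 ± 0.37, Junb at -2.19 ± 0.35 and Ier3 at -1.62 ± 0.35 (adjusted p at most 0.0351). The immediate early list had a median of -0.91 (-0.91 with slide as a block, -0.53 and -1.07 within slides), at an adjusted p = 1.01e-04 and an adjusted p = 0.774 with an estimated correlation. Ribosome biogenesis had 1 negative and 20 not passing (3 negative adjusted over the list alone), with Myc at -1.79 ± 0.41 (adjusted p = 0.047). The ribosome list had a median of -0.35 (-0.31 with slide as a block, -0.34 and -0.10 within slides), at an adjusted p = 0.00628 and an adjusted p = 0.82 with an estimated correlation. Glucocorticoid genes had a median of -0.53 (-0.54 with slide as a block, -0.42 and -0.52 within slides), at an adjusted p = 0.0152 and an adjusted p = 0.82 with an estimated correlation. The 1 passing gene, Lcn2, went against it at 2.85 ± 0.62 (adjusted p = 0.0351; 2 positive adjusted over the list alone).

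**Figure D4:**
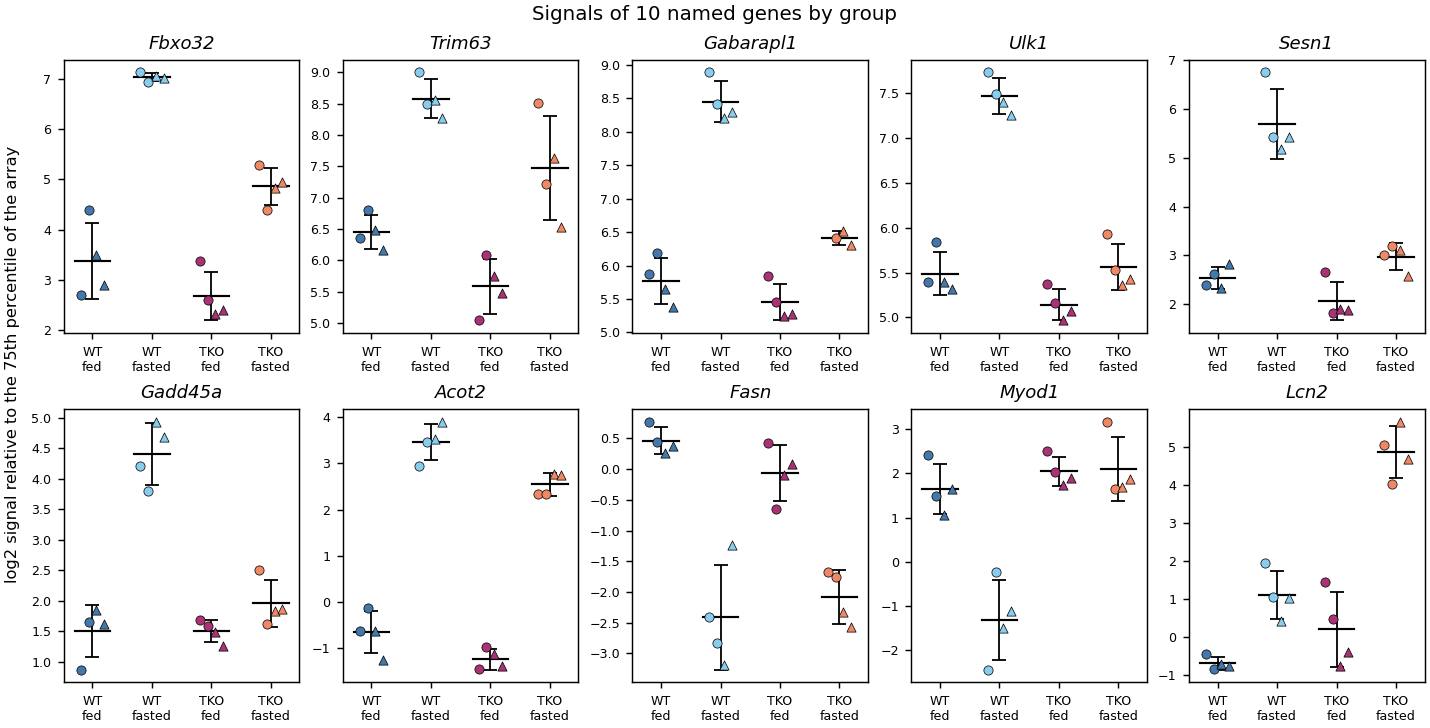
Log2 signal of 10 genes relative to the 75th percentile of each array, 1 point per array with the mean and SD of each group of 4. Fbxo32 rose by 3.67 with fasting in WT and 2.19 in mFoxO-TKO mice.

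Lists without a passing gene were called too. Proteasome subunits had a median interaction of -0.36 (-0.36 with slide as a block, -0.34 and -0.34 within slides), at an adjusted p = 7.08e-05 and an adjusted p = 0.82 with an estimated correlation. Of the subunits 0 of 32 passed in limma (0 adjusted over the list alone), against 5 negative at an unadjusted p under 0.05. Antioxidant genes had a median of -0.26 (-0.26 with slide as a block, -0.29 and -0.28 within slides), at an adjusted p = 0.0065 and an adjusted p = 0.82 with an estimated correlation. Of 19 antioxidant genes 0 passed in limma (3 negative adjusted over the list alone), against 6 negative and 1 positive at an unadjusted p under 0.05. Fatty acid synthesis had a median of 0.47 (0.45 with slide as a block, 0.63 and 0.00 within slides), at an adjusted p = 0.0182 and an adjusted p = 0.82 with an estimated correlation. Of 16 synthesis genes 0 passed in limma (1 positive adjusted over the list alone), against 3 positive and 1 negative at an unadjusted p under 0.05. Fatty acid use had a median of 0.06 and no call (adjusted p = 0.734), with 0 of 34 passing in limma (0 adjusted over the list alone, and 0 at an unadjusted p under 0.05).

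Single genes with large interactions included Aqp4 (3.08 ± 0.40), Myod1 (3.02 ± 0.61), Fgf5 (2.69 ± 0.50), Mpp3 (2.65 ± 0.41), the carbonic anhydrase gene Car9 (2.36 ± 0.26) and Mamstr (2.35 ± 0.29), a partner of MEF2, each with an adjusted p of at most 0.0234. On the negative side stood Rnf39 (-3.93 ± 0.74), Tmem132e (-3.57 ± 0.38), Rassf4 (-3.31 ± 0.39), Slc43a1 (-2.85 ± 0.37), Doc2b (-2.84 ± 0.53), Sesn1 (-2.25 ± 0.42), Pfkfb3 (-2.06 ± 0.29), Odc1 (-1.83 ± 0.30), Slc2a1 (-1.53 ± 0.31) and Igf1r (-1.36 ± 0.25), each with an adjusted p of at most 0.0284. In all the interaction passed for 244 of 21280 genes, 90 positive and 154 negative (36.9% positive). That share was 48.4% in the authors' value table, 24.9% without fasted mFoxO-TKO replicate 1 and 18.7% with the 2 arrays farthest from their groups left out. For 230 of the 244 the WT change was the larger in size, 150 of them higher and 80 lower in fasted WT mice, for 14 the mFoxO-TKO change was the larger, and for 87 the signs in the genotypes were opposite. With slide as a block 564 genes passed, within slide 1 alone 5 and within slide 2 alone 60. All 29 genes named for the interaction kept their direction on both slides and passed with slide as a block, none of them within slide 1 and 8 within slide 2. Of these 7 lost their call without some 1 array and 15 in another setting, including Tmem132e and Junb with another background correction (adjusted p = 0.381 and 0.194). The count rose to 437 without fasted mFoxO-TKO replicate 1 and fell to 133 without fed WT replicate 4.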

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

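The tests chosen after the result was seen are those of slide, weaker signal and macrophages for the development genes, of a local change of the DNA, and of other cell types, the patch and the patch alone for fasted mFoxO-TKO replicate 1.

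Values far from the other 3 arrays of their group were picked out by the gap to the nearest array over the group's whole range. Of 359 gene and group values 28 were set apart (7.8%, where chance gives about 1 in 20 groups), 9 of them on fasted mFoxO-TKO replicate 1. On that array Rnf39 (0.882), Psmd11 (0.877), Psme4 (0.852), Ctsl (0.886), Igf1r (0.954), Myod1 (0.847), Txnrd1 (0.935) and Fdft1 (0.942) were higher and Gclm (0.845) lower than on the rest of the group. Fasted mFoxO-TKO replicate 3 was higher for Mlph (0.847) and Odf3l2 (0.913) and lower for Pnpla2 (0.925), and replicate 2 was lower for Lox (0.911). In fasted WT mice replicate 1 was higher for Depp1 (0.89), Sesn1 (0.84) and Cry2 (0.959), and replicate 2 lower for Ctsl (0.977). In fed WT mice replicate 4 was higher for Olfr437 (0.841) and Chrna1 (0.908) and lower for Olfr1000 (0.831), replicate 1 higher for Tmem132e (0.842) and lower for Igf1r (0.934), and replicate 2 higher for Ulk1 (0.833). In fed mFoxO-TKO mice replicate 1 was higher for Olfr996 (0.973), Rnf39 (0.945) and Sesn1 (0.895), replicate 3 lower for Psmd11 (0.887) and replicate 4 lower for Myh3 (0.854). Of 12 array measures 1 was set apart, the percent of spots well above background on fed WT replicate 4 (0.899).

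The fasting effect differed between the genotypes by the interaction test. As the effect in mFoxO-TKO minus that in WT mice it was positive for Aqp4 (3.08), Myod1 (3.02), Lcn2 (2.85), Fgf5 (2.69), Mpp3 (2.65), Car9 (2.36) and Mamstr (2.35). It was negative for Rnf39 (-3.93), Depp1 (-3.74), Tmem132e (-3.57), Rassf4 (-3.31), Slc43a1 (-2.85), Doc2b (-2.84), Chac1 (-2.8), Gadd45a (-2.46), Sesn1 (-2.25), Maff (-2.24), Junb (-2.19), Pfkfb3 (-2.06), Odc1 (-1.83), Myc (-1.79), Gabarapl1 (-1.72), Ier3 (-1.62), Ulk1 (-1.57), Slc2a1 (-1.53), Fbxo30 (-1.47), Igf1r (-1.36), Ctsl (-1.28) and Slc7a1 (-0.895). Among lists the median difference was -0.906 for immediate early genes, -0.533 for the glucocorticoid response, -0.362 for proteasome subunits, -0.35 for ribosome biogenesis, -0.338 for ATF4 targets, -0.279 for autophagy and lysosome, -0.264 for antioxidant defence and 0.472 for fatty acid synthesis. Camera lost these calls with an estimated correlation.

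Myh3, Chrna1, Chrnd, Ncam1, Igf2, Mest, Dclk1 and Mymk were higher on 3 of the 4 arrays of fed mFoxO-TKO mice, with medians of 2.28, 2.17 and 1.498 above fed WT on replicates 1 to 3 and 0.30 on replicate 4, where 7 of the 8 still lay above every fed WT array. A difference between slides is argued against as the whole cause by the median difference of 0.9209 between replicates 3 and 4, which share slide 2, where fed WT replicates 3 and 4 differed by at most 0.398. Weaker signal is argued against by 68.94% of spots well above background on replicate 4, at or above replicates 1 to 3. Macrophages entering damaged muscle stay open. The macrophage median was higher than on replicate 4 by 1.042 and 1.096 on replicates 1 and 2, and by 0.2469 on replicate 3, which is within the SD of 0.458 between fed WT arrays. In fasted mFoxO-TKO mice Ncam1 (-1.18, adjusted p = 0.00696) and Igf2 (-1.36, adjusted p = 0.0167) were lower than in fed ones, as were Myh3, Mest, Dclk1 and Mymk. Mest and Dclk1 were lower in fasted WT mice too. All 4 fed mFoxO-TKO arrays lay in 1 column, so column does not set replicate 4 apart. Renewal of muscle fibres in some fed mice was not tested and stays open.

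Neighbouring genes were higher in mFoxO-TKO mice in both feeding states, among them Olfr996, Olfr998 and Olfr1000 on chromosome 2, and Cd5 and Tmem132a on chromosome 19, the last pair chosen after their values were seen. A local change of the DNA or of its activity stays open. The 5 pairs within 5 tested genes of each other exceed the mean of 1000 random placements (1.27), of which 11 gave as many and the highest 8, and 3 of the 5 pairs lie among these Olfr genes. DNA of another strain around Foxo1, Foxo3 and Foxo4 stays open, since 2 of the 120 nearest tested genes were called in both knockout comparisons, where chance gives 1.05 (exact hypergeometric p = 0.284, computed over genes). One transcript read by the probes of several related genes also cannot be told apart from separate transcripts, since 1 of 1058 olfactory receptor genes farther away was raised against 2 of 16 nearby, with only 4 genes of other families near enough to test (0 raised). The labels name no group that would test a biological explanation.

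The array of fasted mFoxO-TKO replicate 1 stood apart on the second principal component, with a median departure of 0.381 from its group against at most 0.252 on the others. Noise of dim spots is argued against by a spread ratio of 2.201 (1.82 to 2.82 on the others). A mixed-up label is argued against by a correlation 0.006705 higher with its own group (0.968) than with any other, and cells of other types by 0 of 7 marker lists beyond the range of the other arrays. A patch of spots with lost signal was found, with 38.31% of held-out bright spots inside it down over 8-fold against 0.201% outside, 132 of its 401 bright spots lost and 14.3% marked by the scanner software. The patch alone is argued against, since without it the correlation with its group was 0.9733, below the lowest other array (0.979). What else sets the array apart stays open, and of the 734 tested genes in the patch 61 rather than 34 passed in the knockout comparison in fasted mice without its spots.

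Chance is argued against, not excluded, for gene counts of 2-group comparisons, since wrong splits mix groups. Of 35 splits only the real one reached 4426 genes (highest other 1) with WT fasting and 1814 (52) in mFoxO-TKO mice. For the knockout it alone reached 217 in fed (1) and 1991 in fasted mice (7). The slide split gave 34 genes in the second of these and 7 in the fourth. For the interaction 4 of 100 splits reached the 244 genes, the real one included. The 3 larger ones (371, 396 and 662) exchanged fed arrays only, so the knockout difference of fasted mice (1991 genes) stayed in the contrast, and they are no clean measure of chance. For the number of lists chance cannot be excluded, with 14 (highest other 16), 12 (18), 6 (17), 9 (16) and 8 (17) lists and 5, 6, 22, 7 of 35 and 40 of 100 splits as high. For the share of 0.56, 5 of 100 splits were as low (lowest 0.4127), but 3 of them are the same splits that exchanged fed arrays only, so this count leaves chance undecided.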

How the results depend on the processing

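Alternatives chosen after seeing the data are those named so under how the data were processed.

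Counts of genes are given in the order fasting effect in WT, fasting effect in mFoxO-TKO, knockout effect in fed mice, knockout effect in fasted mice and interaction of knockout and fasting, where the values reported were 4426, 1814, 217, 1991 and 244. Fewer genes passed at an adjusted p under 0.01 (2585, 719, 90, 1053 and 67) and with a change of at least 1 on the log2 scale (1865, 876 and 936 for fasting in WT, fasting in mFoxO-TKO and knockout in fasted mice), as stricter thresholds must. With slide as a block 2800, 422, 3027 and 564 genes passed in the last 4, and with the replicate number as a block 3181, 410, 3373 and 697. Arrays of the same number correlated above those of other numbers on the same slide (median 0.186 against 0.111), over 0.1 in 23 of 24 pairs (lowest 0.0555) against 14 of 24, with 13 of 16 arrays closest to their own number. As 1 pair fell short, mice were not paired. Equal numbers share a slide row, so row or shared origin stays open. Within slide 1 alone, with fewer arrays, 741, 67, 352 and 5 genes passed (all but the knockout in fed mice), and within slide 2 alone 33 for the knockout in fed mice and 60 for the interaction.

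For the other settings the cause was not tested. Scaling on probes well above background on all arrays gave 2946, 393, 3399 and 612 in the last 4 comparisons, and arrayWeights 4257 for fasting in mFoxO-TKO, 940 for the knockout in fed mice and 829 for the interaction. No filter on dim probes gave 992, 109 and 79 for the same 3, with 36720 genes tested. Using only the groups of the contrast gave 947 for fasting in mFoxO-TKO and 894 for the knockout in fasted mice, and could not give a value for the interaction or the share. The value table gave 367 for the knockout in fed mice and 708 for the interaction, normexp 133 for the knockout in fed mice, and for the interaction the array median gave 155, marked spots kept 427 and the 2 farthest arrays left out 411. Of 49 list calls 1 stood with an estimated correlation, and fry made 26 calls, ending 25 of these and adding 2. The share of the WT fasting response was 0.4173 within slide 1. Of 131 values of the counts, list total and share under settings other than single slides and single arrays, 95 kept within 1.5 times, 19 were higher and 17 lower.

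Leaving out each array in turn gave 3443 to 5411, 1078 to 2113, 105 to 311, 1533 to 2301 and 133 to 437 genes, 46 to 59 lists and a share of 0.4988 to 0.5832. Fasting in mFoxO-TKO fell to 1078 without fed mFoxO-TKO replicate 2, 1204 without its replicate 3 and 1085 without fasted mFoxO-TKO replicate 3. The knockout in fed mice fell to 115, 105 and 121 without fed WT replicates 1, 2 and 3 and to 136, 122 and 119 without fed mFoxO-TKO replicates 1, 2 and 3. The interaction fell to 155, 155 and 133 without fed WT replicates 1, 3 and 4, to 144 and 148 without fed mFoxO-TKO replicates 2 and 3 and to 149 and 143 without fasted mFoxO-TKO replicates 2 and 4, and rose to 437 without its replicate 1.

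Of the named genes 1 reversed, Fdft1 with fasting in WT mice, at -0.2383 by its dimmest kept probe. Within slide 2 alone the endothelial list reversed for the knockout in fed mice (0.181 against -0.195). For smooth muscle and pericytes camera's direction turned from lower to higher while the median kept its sign (0.2617 against 0.02137). Leaving out 1 array kept 3061 calls of named genes and ended 235, other settings kept 3237 and ended 134, and single slides kept 232 and ended 180. For lists those settings kept the side of the threshold in 2203, 2504 and 237 cases, added a call in 83, 115 and 34 and ended one in 34, 107 and 17. The planned normexp correction on mean signals was not run. Signal over background limits what can be measured for dim genes, as Foxo3 and the genes given only as bounds.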

Other observations

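No test in this part was chosen after the result was seen, and the lists were written before the data were examined.

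The lists of mitochondrial and contractile genes were not called in any comparison. Of 27 genes of respiration and the TCA cycle 0 passed in limma in each of the 5 comparisons, and at an unadjusted p under 0.05 only 1 did, lower in fed mFoxO-TKO mice. The medians were 0.07 and 0.16 for fasting in WT and mFoxO-TKO mice and -0.06 and -0.02 for the knockout in fed and fasted mice (list adjusted p = 0.729, 0.373, 0.292 and 0.747). The 10 slow fibre genes had medians of 0.04, 0.33, 0.13 and 0.38 in the same order (adjusted p = 0.865, 0.141, 0.3 and 0.0536) and the 13 fast fibre genes 0.05, 0.10, -0.08 and -0.02 (adjusted p = 0.92, 0.439, 0.37 and 0.837). Of the slow fibre genes 0 passed in limma, against 1 higher and 1 lower with fasting in mFoxO-TKO mice and 2 higher for the knockout in fasted mice at an unadjusted p under 0.05. Of the fast fibre genes 1 was lower with fasting in WT mice and 1 higher for the knockout in fasted mice. Heat shock genes had 2 of 10 higher with fasting in each genotype and medians of 0.12, 0.28, -0.01 and -0.10 (adjusted p = 0.254, 0.141, 0.698 and 0.719).

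As lists, markers of further cell types were not called in any comparison, while single markers passed with fasting. Adipocyte markers had 1 higher and 2 lower of 8 in WT and 1 higher and 1 lower in mFoxO-TKO mice. Endothelial markers had 1 lower of 10 in WT and 1 higher in mFoxO-TKO mice, and nerve markers 1 higher of 7 in WT mice. With fasting in WT and mFoxO-TKO mice and for the knockout in fed and fasted mice the medians were -0.31, -0.19, -0.30 and -0.15 for adipocytes, -0.09, 0.25, -0.20 and 0.12 for endothelium, -0.23, 0.03, 0.02 and 0.12 for smooth muscle and pericytes, -0.12, 0.44, -0.04 and 0.31 for nerve and Schwann cells and 0.16, 0.41, -0.12 and 0.13 for erythroid cells. In the interaction the medians were 0.12 for mitochondria, 0.26 for slow and 0.10 for fast fibre genes, -0.02 for heat shock, 0.23 for adipocytes, 0.37 for endothelium, 0.14 for smooth muscle, 0.33 for nerve and 0.24 for erythroid cells.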
